A study of Homo sapiens with 60 samples.

How the data were processed

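RNA-seq libraries of A549 cells, a human non-small cell lung carcinoma line, were compared after 24 hours with a water extract of a tonifying herb or formula, or with vehicle. The deposited table held expected counts per gene, with 1 column per library and no scaling between libraries. Per the submitters' processing notes, the tools were FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3, and the genome builds named were hg38 and GRCh38. The annotation release, the strand setting and any filters were not given in the sources used here. Between 7.66 and 10.04% of the values of a library had decimals, and the values were rounded to whole numbers before modelling. The table had 60675 genes and 270 columns, of which 60 were used; the other 210 columns match no sample here and were not analysed. Symbols were found for 56558 of the gene identifiers, and 57055 were found in GENCODE release 29, which gave positions and gene types. Genes at 0 in all 60 libraries numbered 21088.

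Groups followed the sample labels. There were 19 groups of 3 libraries, which entered the models with 57 libraries, and 3 libraries of the Palmul-tang extract, 1 per dose, which were compared by value without a test. Library totals lay between 20204604 and 39755705 counts, and the second highest total was 27537934. Counts were normalised by TMM in edgeR 4.0.16 (R 4.3.3), with factors between 0.869 and 1.048. Genes with low counts were removed with filterByExpr, which left 16979. A quasi-likelihood model with 1 mean per group was fitted to the 57 libraries, its common dispersion was 0.00266, and its median biological coefficient of variation was 0.0504. The model gave 29 two-sided comparisons: each extract and dose with vehicle, the high with the low dose of each extract, and pairs of extracts at the high dose. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Standard errors (SE) of log2 fold changes were the fold change divided by the square root of the F statistic. CPM values used the TMM-scaled library sizes and are given with the standard deviation (SD) between libraries.

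Of 30 gene lists, 28 had at least 3 measured members and were tested. They were compared with all other genes by limma camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. The test was repeated with an estimated correlation, and p was adjusted over lists and comparisons of a family. Lists, comparisons, alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each high dose against vehicle, the 6 largest rises and 6 largest falls among called genes with at least 5 CPM in one group and all 3 treated libraries on one side of all 3 vehicle libraries. It took 3 and 3 genes likewise for the high against the low dose and for pairs of extracts, the 4 members with the smallest p of each list, and 5 and 5 genes for Palmul-tang. List counts are given over all genes tested and adjusted over the list alone.

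The procedure was tested on simulated data with 16979 genes: it called 98 of 100 genes changed by 1 and 85 of 100 changed by 0.5 on the log2 scale, 13 unchanged genes, and 0 genes in a comparison without change. All simulated libraries had the same spread per gene, and none stood apart as vehicle replicate 3 did in the data. The simulation therefore does not cover the real comparisons with vehicle. The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, a fit of only the 6 libraries compared, the replicate number as a block, an estimated correlation for lists, another prior count, and leaving out each library in turn; the similarity of extracts was also taken from high against low and from abundant genes. Leaving out the mitochondrial genes, and leaving out vehicle replicate 3 and Cnidii high replicate 2 together, were added after seeing the data, as were the gene lists without vehicle replicate 3. Figures were drawn with matplotlib 3.10.9.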

Results

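The samples came from A549 cells, a human lung carcinoma line, treated for 24 hours with water extracts at a high, medium or low dose (500, 100 and 20 µg/mL). The extracts were Cnidii Rhizoma, Rehmanniae Radix Preparata, Cinnamomi Cortex, Astragali Radix and the formulas Sagunja-tang, Samul-tang and Palmul-tang, called below by their first word. Samul contains Cnidii and Rehmanniae among its herbs, and Palmul combines Sagunja and Samul. Each dose of the first 6 extracts, and the vehicle, had 3 libraries, and each dose of Palmul had 1. Vehicle was DMSO, at 0.1% in the sample labels and 2% in the series description. Library totals ranged from 20204604 to 39755705 counts. The labels do not say whether the 3 replicates were grown apart, so p values measure only the spread between these libraries. The sample codes put Cnidii and Rehmanniae in set 5, Cinnamomi and Astragali in set 6, Sagunja and Samul in set 7, and Palmul alone in set 8. All sample titles, vehicle included, name batch B, and the labels do not say what the first part of the sample code marks. By that code vehicle was in a set of its own, so that code set and extract against vehicle cannot be separated.

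The genes of the mitochondrial genome made up 25.2% of the counts of vehicle replicate 3, and 17.6 and 17.5% in the other vehicle libraries. In the 54 extract libraries this share lay between 13.85 and 19.12%. The comparisons with vehicle asked what each extract changed, and most of their counts moved with that library. The number of genes called with Cnidii at the high dose was 1106 with all vehicle libraries and 47 without vehicle replicate 3, of which 44 were shared. At the high dose, Rehmanniae called 390 and then 55 genes (44 shared), Astragali 585 and 37 (33 shared), Sagunja 2549 and 271 (255 shared), Samul 2119 and 315 (275 shared) and Cinnamomi 9424 and 8595 (8053 shared). In an edgeR fit of only the 6 libraries compared, the counts at the high dose were 4 for Cnidii, 3 for Rehmanniae, 0 for Astragali, 3 for Sagunja and 0 for Samul. The Astragali and Samul fits that called 0 genes had 1197 and 2271 genes at an unadjusted p under 0.05, and DESeq2 on all 57 libraries called 951 and 2317. The plot of genes called with and without this library shows all 18 comparisons.

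**Figure D1:**
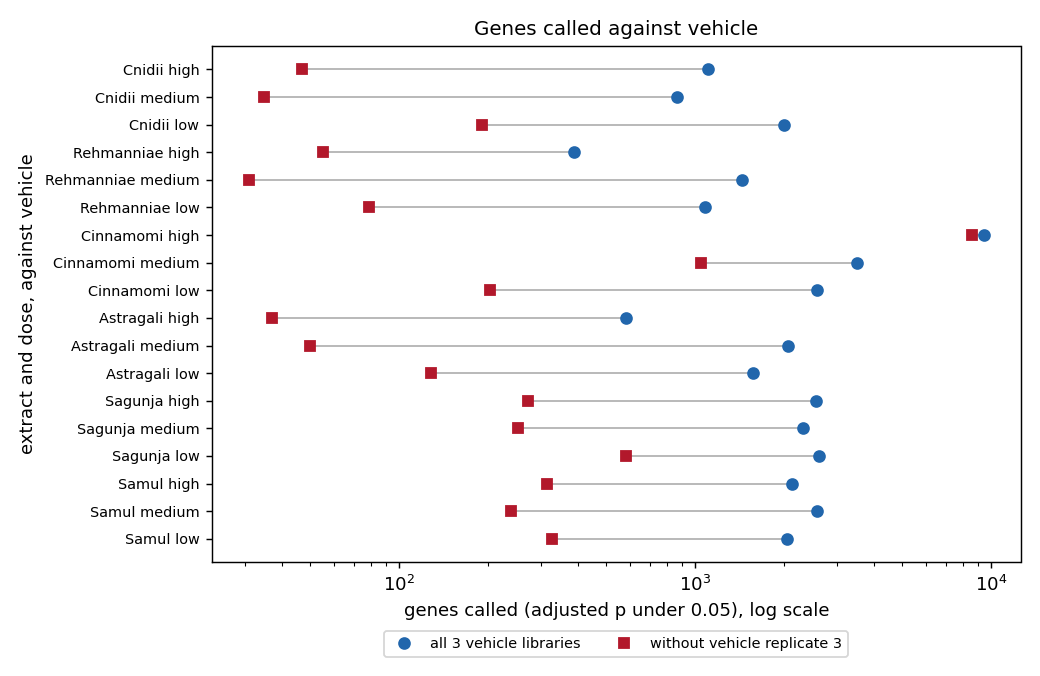
Number of genes called against vehicle (adjusted p under 0.05, log axis) for each of 6 extracts at 3 doses, with all 3 vehicle libraries (circles) and without vehicle replicate 3 (squares). Cinnamomi at the high dose went from 9424 to 8595 genes, while Cnidii at the high dose went from 1106 to 47.

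Cinnamomi at the high dose had the highest number of genes called against vehicle. At the high dose 4510 genes were higher and 4914 lower than in vehicle, with 158 at least 2-fold higher and 1483 at least 2-fold lower. ALDOC, a glycolytic aldolase (ENSG00000109107, hg38 chromosome 17, 28573115 to 28577264), rose from 11.4 ± 1.01 to 32.6 ± 0.703 CPM (SD, n = 3), a log2 change of 1.51 ± 0.09 (SE, edgeR adjusted p = 2.5e-19). HMOX1, which degrades heme, rose by 1.06 ± 0.08, and the lysosomal protease CTSD by 0.81 ± 0.06. GOLGA8A (ENSG00000175265, chromosome 15, 34379068 to 34437466) went from 61.1 ± 11.95 to 5.36 ± 1.14 CPM, a log2 change of -3.49 ± 0.15. SEC31B and WDR97 changed by -3.26 ± 0.21 and -3.04 ± 0.18. GOLGA8A shares reads with near copies, so its own level is uncertain.

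The genes called with Cinnamomi were counted by list. Of the cholesterol synthesis list, 21 of 24 measured members rose and 2 fell (21 and 2 adjusted over the list alone). Among them were TM7SF2, a sterol reductase (1.07 ± 0.07), FDFT1, which makes squalene (0.61 ± 0.04), and DHCR7, which makes cholesterol from its last precursor (0.79 ± 0.06). Of the NRF2 targets, antioxidant genes, 21 of 25 rose and 2 fell, with the quinone reductase NQO1 at 0.65 ± 0.05. Of the autophagy and lysosome genes 19 of 20 rose and 0 fell, and of the hypoxia and HIF genes 13 of 19 rose and 1 fell, with the glucose transporter SLC2A1 at 0.82 ± 0.05 and the carbonic anhydrase CA9 at 0.83 ± 0.06. Cytosolic ribosomal proteins rose in 30 of 31 cases and fell in 0 (31 adjusted over the list alone), with RPLP0 at 0.79 ± 0.07. Mitosis genes fell in 15 of 22 cases and rose in 2 (16 and 2 adjusted over the list alone): the kinetochore proteins CENPE (-2.21 ± 0.13) and CENPF (-1.09 ± 0.07) and the proliferation marker MKI67 (-1.84 ± 0.12). NF-kB and inflammation genes fell in 12 of 21 cases and rose in 0, with the NF-kB inhibitor TNFAIP3 at -0.91 ± 0.09 and the chemokine CXCL2 at -0.91 ± 0.12. By limma camera the adjusted p was 4.7e-09 for cholesterol synthesis, 1.5e-07 for NRF2 targets, 6.7e-08 for lysosome, 5.7e-07 for hypoxia, 2.3e-13 for ribosomal proteins, 0.000105 for mitosis and 0.00484 for NF-kB. With an estimated correlation the adjusted p was 0.0462 for mitosis, and the other calls were lost: adjusted p = 0.0616 for cholesterol, NRF2, lysosome and hypoxia, 0.149 for ribosomal proteins and 0.171 for NF-kB.

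The large falls with Cinnamomi were uneven between gene types. Of 13618 protein-coding genes tested 4.51% were at least 2-fold lower, against 25.8% of 871 pseudogenes and 25.9% of 2382 other noncoding genes. Symbols starting with GOLGA6 or GOLGA8 were 2-fold lower in 9 of 13 cases, and those starting with NPIP in 16 of 19; these gene sets were chosen after their values were seen, and their members share reads. The rule for named genes gave 12 genes, of which 11 kept their call when any library was left out. SMIM11, which also shares reads with a copy, lost its call without vehicle replicate 2 (adjusted p = 0.0557).

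The dose series asked whether the Cinnamomi response grew with dose. Between the high and the low dose 3959 genes rose and 4097 fell. ALDOC was 1.51, 0.39 and 0.26 above vehicle at the high, medium and low dose (log2), while HMOX1 was at 1.06, 0.12 and -0.13, of which the latter 2 were not called. MKI67 was at -1.84, -0.55 and -0.56. INSIG1, which holds back sterol synthesis, was 0.25 above vehicle at the high dose and at -0.37 and -0.44 at the medium and low dose. From the low to the high dose cholesterol synthesis genes rose in 22 of 24 cases and fell in 1 (adjusted p = 2.2e-12 by limma camera, 0.0182 with an estimated correlation), lysosome genes rose in 17 of 20 and fell in 0 (2.0e-08 and 0.0383), NRF2 targets rose in 21 of 25 and fell in 2 (2.5e-07 and 0.0397), and the targets of the aryl hydrocarbon receptor (AHR) rose in 5 of 10 and fell in 1 (0.00309 and 0.0291). Mitosis genes fell in 10 of 22 cases and rose in 2, and the list did not pass (0.0576 and 0.276). Hypoxia genes rose in 13 of 19 cases and fell in 1 (adjusted p = 7.3e-05), ribosomal proteins rose in 29 of 31 and fell in 0 (4.2e-11), and NF-kB and inflammation genes fell in 9 of 21 and rose in 0 (0.0299), and these calls were lost with an estimated correlation (0.117, 0.181 and 0.264). Mitochondrially encoded genes rose in 10 of 13 cases and fell in 0 (0.00978, and 0.561 with an estimated correlation). The TMM factors of the Cinnamomi high libraries were 0.869, 0.877 and 0.909, and apart from vehicle replicate 3 (0.892) no other library was below 0.966. The counts against vehicle at the medium and low dose were 3505 and 2580, and 1045 and 202 without vehicle replicate 3. In edgeR fits of only the 6 libraries compared they were 9 and 0; the fit that called 0 had 1788 genes at an unadjusted p under 0.05, and DESeq2 called 2716.

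**Figure D2:**
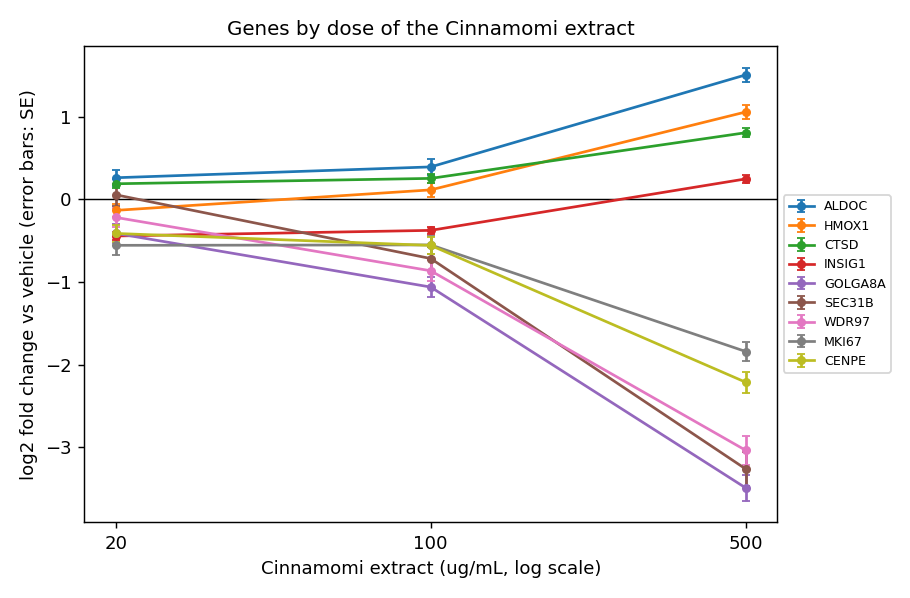
Log2 fold change against vehicle (vertical axis, error bars SE) of 9 genes at 20, 100 and 500 µg/mL of the Cinnamomi extract (log axis), 3 libraries per dose. ALDOC went from 0.26 to 1.51 and GOLGA8A from -0.41 to -3.49 between the low and the high dose.

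Against Astragali, which shares its code set, Cinnamomi at the high dose had 4284 genes higher and 4365 lower. ALDOC was higher by 1.80 ± 0.09 and HMOX1 by 1.14 ± 0.08 (log2), and SEC31B was at -3.50 ± 0.20. Cholesterol synthesis genes were higher in 22 of 24 cases and lower in 1. INSIG1 was among the higher ones (0.85 ± 0.05), and the list had an adjusted p of 6.2e-14 by limma camera (and 0.0104 with an estimated correlation). Hypoxia genes were higher in 14 of 19 cases and lower in 1 (5.4e-08 and 0.0371), and genes driven by the stress factor ATF4 in 13 of 20, with 2 lower (0.00106 and 0.028). Mitosis genes were lower in 12 of 22 cases and higher in 2 (adjusted p = 0.00498), and ribosomal proteins higher in 31 of 31 (9.2e-13), and both calls were lost with an estimated correlation (0.102 and 0.149). NF-kB and inflammation genes, 8 of 21 lower and 2 higher, did not pass as a list (0.0733 and 0.386). Of the 6 genes the rule named, 5 kept their call when any library was left out, and ENSG00000277991 lost it without Cinnamomi high replicate 2 (adjusted p = 0.0548) or 3 (0.0653) or Astragali high replicate 1 (0.0595) or 3 (0.0533).

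Genes of cell division were higher at the high than at the low dose of Rehmanniae and of Samul. This difference alone does not tell a rise at the high dose from a lower level at the low dose. In the single Palmul libraries the mitosis median was 0.065 (log2 from the vehicle mean) at the high and -0.274 at the low dose. Of 22 measured mitosis genes, 19 were higher at the high than at the low dose of Rehmanniae (22 adjusted over the list alone), and 21 with Samul (22 adjusted over the list alone), and 0 were lower in both. With Rehmanniae the spindle checkpoint kinases BUB1B and TTK rose by 0.36 ± 0.05 and 0.38 ± 0.05 (log2), CDC20, which starts anaphase, by 0.32 ± 0.05, and the hyaluronan receptor HMMR by 0.42 ± 0.06. With Samul the topoisomerase TOP2A rose from 311.6 ± 3.93 to 400.0 ± 4.06 CPM (0.36 ± 0.04), the spindle motor KIF11 by 0.32 ± 0.04 and DLGAP5 by 0.43 ± 0.04. DNA replication genes rose in 12 of 21 cases with each extract (16 adjusted over the list alone) and fell in 0, among them the helicase subunit MCM4 (0.21 ± 0.03 with Rehmanniae, 0.26 ± 0.03 with Samul) and the nucleotide reductase RRM2 (0.25 ± 0.04 and 0.24 ± 0.04). By limma camera the adjusted p for mitosis was 2.0e-51 with Rehmanniae and 9.5e-55 with Samul, and 7.9e-12 and 5.7e-12 with an estimated correlation.

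Targets of the AHR, a receptor for aromatic compounds, rose with Samul as well. CYP1B1, which oxidises such compounds, rose from 128.8 ± 2.06 to 175.8 ± 6.23 CPM between the low and the high dose (0.45 ± 0.04), ALDH3A1 by 0.43 ± 0.05 and CYP1A1 from 0.248 ± 0.0938 to 1.13 ± 0.293 CPM (2.15 ± 0.39). These were 3 of 10 list members, and 0 fell (adjusted p = 3.9e-06 by limma camera, 0.000834 with an estimated correlation). With Rehmanniae CYP1B1 and ALDH3A1 rose by 0.23 and 0.29, and HMOX1 by 0.47 ± 0.08. Among the falls named by the rule was the Wnt inhibitor DKK1 with Samul (-0.51 ± 0.08). In all, 161 genes rose and 86 fell with Rehmanniae, and 227 rose and 135 fell with Samul. When 1 library was left out, the totals lay between 107 (without Rehmanniae high replicate 1) and 162 (without Rehmanniae high replicate 2), against 247 with all libraries, and between 182 (without Samul high replicate 1) and 231 (without Samul high replicate 2), against 362. Left-out libraries ended the Rehmanniae calls of CEP128 (adjusted p = 0.106 without Rehmanniae low replicate 1), CLDN2 (0.0844 without the same library) and CES4A (0.145 without Rehmanniae low replicate 2, 0.132 without high replicate 3 and 0.0682 without high replicate 1), and the Samul calls of CLDN2 (0.0512) and CRYAB (0.0967) without Samul low replicate 1. In the fit of only the 6 libraries compared, Rehmanniae had 448 genes.

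**Figure D3:**
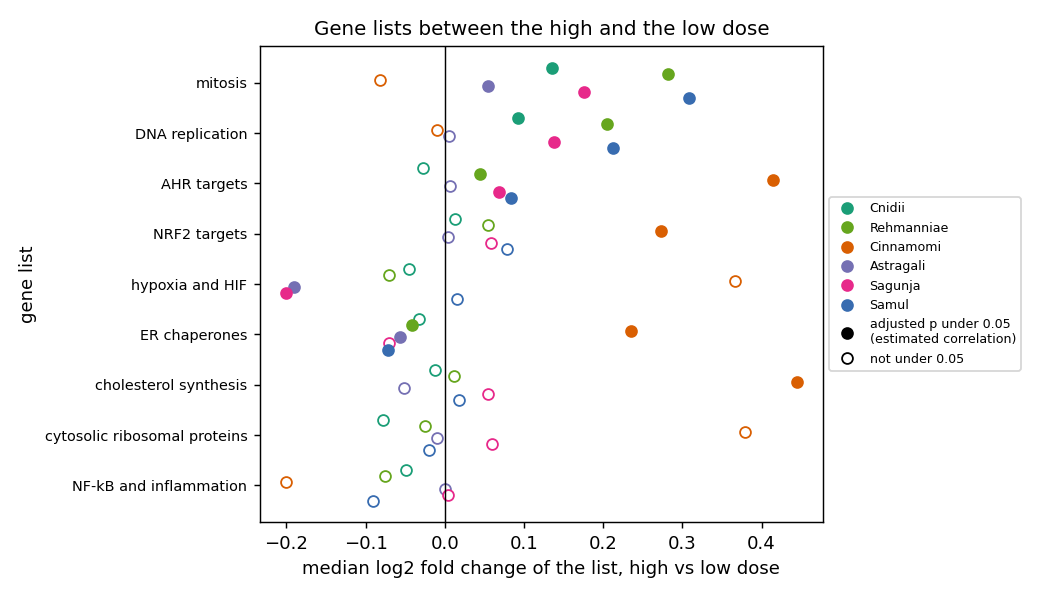
Median log2 fold change between the high and the low dose (horizontal axis) of 9 gene lists for 6 extracts, filled where the adjusted p of limma camera with an estimated correlation was under 0.05. The mitosis medians were 0.31 with Samul and 0.28 with Rehmanniae.

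Against vehicle, Rehmanniae and Samul at the high dose raised AHR targets. With Rehmanniae 3 of 10 were higher and 0 lower (CYP1B1 0.23 ± 0.04, ALDH3A1 0.24 ± 0.05), with an adjusted p of 0.000213 by limma camera and 0.0293 with an estimated correlation. With Samul 5 of 10 were higher and 0 lower (CYP1B1 0.44 ± 0.04), with adjusted p values of 8.3e-07 and 0.00325. Mitosis genes were higher in 5 of 22 cases with Rehmanniae (11 adjusted over the list alone) and 7 of 22 with Samul (10 adjusted over the list alone), and lower in 0 (estimated correlation: adjusted p = 0.00834 and 0.0315). Samul also had hypoxia genes higher in 7 of 19 cases and lower in 0, led by the oxygen sensor EGLN3 at 0.62 ± 0.09 (adjusted p = 3.7e-07, and 0.0616 with an estimated correlation), and NF-kB and inflammation genes lower in 7 of 21 cases and higher in 0, such as NFKB2 at -0.32 ± 0.06 (adjusted p = 8.4e-05, and 0.0616 with an estimated correlation). In total 176 genes were higher and 214 lower with Rehmanniae, and 1012 were higher and 1107 lower with Samul, while 55 and 315 genes were called without vehicle replicate 3. Of 12 named genes each, 3 with Rehmanniae and 2 with Samul (RFX3, a ciliary transcription factor, at 0.73 ± 0.12, and the ciliary motor DNAH5 at 0.62 ± 0.14) kept their call when any library was left out. Without vehicle replicate 3 the Samul calls of RPS21 (adjusted p = 0.372), FCGBP (0.0508) and MT-ND6 (0.471) ended, for example, and that of RPS21 also ended without Samul high replicate 2 (0.0748) or 3 (0.0684).

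The 3 Rehmanniae genes that kept their call were ENSG00000280800, ENSG00000280614 and ENSG00000281181, noncoding genes at chromosome 21, 8210384, 8393419 and 8437629, which share reads with one another. They were taken here as a measure of ribosomal RNA in each library. ENSG00000280800 was at 376.8 ± 28.5 CPM against 1328 ± 233 in vehicle, a log2 change of -1.82 ± 0.31. Their summed level averaged 1247.5 ± 227.1 CPM (SD) over the 18 libraries of set 5, 5215.8 ± 1797.9 over the 18 of set 6, 5663.4 ± 785.9 over the 18 of set 7, and 3725.8 ± 808.8 over the 3 vehicle libraries. The libraries of set 5 reached at most 1978.8 CPM, while set 6 ranged from 1416.6 to 9420.1 and overlapped with both other sets, and set 7 ranged from 4385.0 to 7019.7. The vehicle libraries ranged from 2802.9 to 4310.9, above all libraries of set 5 at each dose of Cnidii and Rehmanniae. The Rehmanniae calls of these genes therefore cannot be told apart from code set.

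Sagunja raised SAA2, CXCL8, CFB and LCN2 at each dose. SAA2, an acute-phase protein (ENSG00000134339, chromosome 11, 18239223 to 18248643), was at 25.9 ± 2.41 CPM at the high dose against 7.00 ± 1.59 in vehicle, a log2 change of 1.87 ± 0.12. At the medium and low dose it was at 28.8 ± 1.89 and 23.3 ± 1.22 CPM. CXCL8, which attracts neutrophils, was at 5.204 ± 0.777 against 2.02 ± 0.419 (1.34 ± 0.18), the complement factor CFB at 12.1 ± 0.101 against 4.84 ± 0.225 (1.32 ± 0.10), and the iron-binding protein LCN2 at 24.5 ± 1.16 against 12.7 ± 1.19 (0.96 ± 0.10). All 9 Sagunja libraries lay above all 48 other replicated libraries for these 4 genes: SAA2 was at 21.9 to 31.0 CPM against 5.55 to 10.2, CXCL8 at 4.20 to 6.06 against 1.11 to 2.44, CFB at 11.2 to 14.8 against 4.63 to 7.55 and LCN2 at 20.2 to 26.9 against 11.2 to 17.3. These 4 genes were chosen for the comparison of all libraries after their values were seen, so their separation is partly built into the choice. SAA2 shares reads with SAA1, and CXCL8 lost its call in the fit of only the 6 libraries (adjusted p = 0.0672). Of 21 NF-kB and inflammation genes 5 were higher and 2 lower than in vehicle (6 and 2 adjusted over the list alone), among them CXCL1 at 0.67 ± 0.09 and CXCL5 at 0.34 ± 0.07, both of which lost their call in the fit of only the 6 libraries (adjusted p = 0.065 and 0.0983). The chemokine CXCL3 was not called (1.735 ± 0.524 CPM against 2.101 ± 0.373 in vehicle, edgeR adjusted p = 0.414). The list did not pass against vehicle by limma camera (adjusted p = 0.0518, and 0.328 with an estimated correlation).

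**Figure D4:**
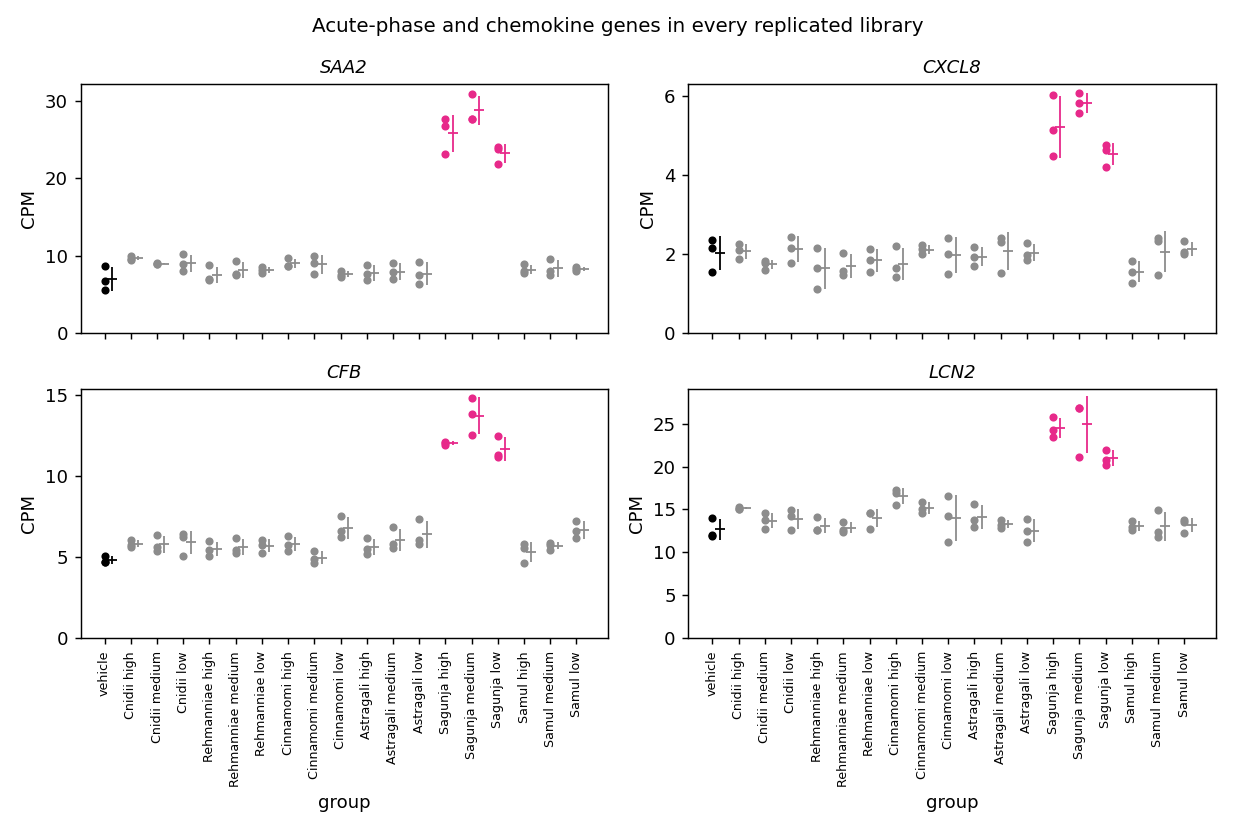
CPM of SAA2, CXCL8, CFB and LCN2 in each of the 57 replicated libraries (points), with the mean and SD of each group of 3 beside them. The 9 Sagunja libraries lie above the other 48 in all 4 panels, with SAA2 at 21.9 to 31.0 CPM against 5.55 to 10.2. The 4 genes were chosen after their values were seen.

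Against Samul at the high dose, which shares its code set, Sagunja had 31 genes higher and 14 lower. CXCL8 was higher by 1.75 ± 0.18, SAA2 by 1.66 ± 0.11, CFB by 1.18 ± 0.10 and CXCL1 by 0.87 ± 0.09 (log2). NF-kB and inflammation genes were higher in 6 of 21 cases (11 adjusted over the list alone) and lower in 0, with an adjusted p of 5.1e-24 by limma camera and 1.0e-06 with an estimated correlation. Mitosis genes were lower in 3 of 22 cases and higher in 0 (adjusted p = 4.7e-16, and 7.6e-06 with an estimated correlation), and the mitotic kinase MELK was at -0.28 ± 0.05. Left-out libraries gave 28 (without Sagunja high replicate 2 or 3) to 34 genes (without Sagunja high replicate 1), against 45 with all libraries, while the fit of only the 6 libraries called 55 and the fit without a low-count filter 137. The calls of BRCA2 and HEG1 each ended whichever of the 6 libraries was left out, with adjusted p up to 0.135 and 0.571. The call of TTK ended without Sagunja high replicate 2 (adjusted p = 0.0948).

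Mitosis genes were higher and hypoxia genes lower at the high than at the low dose of Sagunja. From the low to the high dose mitosis genes rose in 10 of 22 cases and fell in 0, such as CDC20 (0.28 ± 0.05), KIF20A (0.32 ± 0.06) and TOP2A (0.22 ± 0.04), with an adjusted p of 2.4e-25 by limma camera and 8.3e-08 with an estimated correlation. Hypoxia genes were lower at the high than at the low dose in 4 of 19 cases and higher in 0, led by CA9 at -0.36 ± 0.06 (2.6e-11 and 0.00982). CA9 was at 68.1 ± 0.967 CPM at the high dose and 87.2 ± 7.22 at the low dose, against 72.5 ± 2.66 in vehicle. The low dose differed from vehicle (0.27, adjusted p = 0.00172) and the high dose was not called (-0.09, adjusted p = 0.339). At the low dose mean CA9 was above vehicle with the other replicated extracts as well, from 83.5 CPM (Rehmanniae) to 91.2 (Cinnamomi). ALDH3A1 rose by 0.43 ± 0.05 and CYP1B1 by 0.34 ± 0.04 from the low to the high dose of Sagunja. The iron carrier TF (-0.77 ± 0.11) and the tight-junction protein CLDN2 (-0.72 ± 0.10) fell. The NF-kB and inflammation list had 0 of 21 members called by edgeR between these doses (adjusted p = 0.785, and 0.922 with an estimated correlation). In all, 90 genes rose and 173 fell, 263 together, and leaving out 1 library gave 97 (without Sagunja high replicate 3) to 165 (without Sagunja high replicate 2). The calls of LEFTY1 (adjusted p = 0.0596) and CENPH (0.148) ended without Sagunja high replicate 1. That of CENPH also ended without Sagunja high replicate 3 (0.236) or Sagunja low replicate 1 (0.183), 2 (0.14) or 3 (0.0847), and that of SNHG10 without Sagunja high replicate 3 (0.452) or Sagunja low replicate 1 (0.236) or 2 (0.0837). Against vehicle 1282 genes were higher and 1267 lower at the high dose, with AHR targets higher in 3 of 10 cases and lower in 0 (estimated correlation: adjusted p = 0.0315). Of 12 named genes 5 kept their call when any library was left out, and the other 7 lost it without vehicle replicate 3, such as MT-ND1 (adjusted p = 0.254) and SULT1A3 (0.288).

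With all 57 libraries and the low-count filter, 4 genes differed between the high and the low dose of Cnidii and 1 with Astragali, while without that filter 112 and 100 did. Between the high and the low dose of Cnidii 2 genes rose and 2 fell: the DNA repair gene BRCA2 (0.39 ± 0.07), the pseudogene REXO1L1P, the aldehyde oxidase AOX1 (-0.25 ± 0.05) and CCDC69 (-0.29 ± 0.05). REXO1L1P, chosen after its values were seen, had 336 counts in Cnidii high replicate 2, the library with 30504 genes above 0, and at most 1 count in each of the other 5 libraries. Its call ended without that library (adjusted p = 1) and also without Cnidii low replicate 1 (0.166), 2 (0.215) or 3 (0.125). Mitosis genes were higher as a list, with a median of 0.14 on the log2 scale (adjusted p = 2.6e-18, and 1.9e-06 with an estimated correlation), although 0 of 22 passed alone by edgeR (12 adjusted over the list alone). The call of BRCA2 ended without Cnidii high replicate 3 (adjusted p = 0.124) or Cnidii low replicate 1 (0.0734) or 2 (0.343). Those of AOX1 and CCDC69 ended without Cnidii high replicate 2 (0.238 for both) or Cnidii low replicate 1 or 2, and that of AOX1 also without Cnidii high replicate 1 (0.078). The Cnidii count was 0 without Cnidii low replicate 1 (1272 genes at an unadjusted p under 0.05) or 2 (796) and 5 without Cnidii low replicate 3, and DESeq2 with all libraries called 15. With Astragali, 1 gene was called lower at the high than at the low dose, CA9 (68.7 ± 3.06 against 86.3 ± 6.64 CPM, -0.33 ± 0.06). In vehicle CA9 was at 72.5 ± 2.66 CPM, so the high dose lay near vehicle (-0.08, adjusted p = 0.49) and the low dose above it (0.25, adjusted p = 0.00662). Mean CA9 was also above vehicle at the low dose of Cnidii (86 CPM), Rehmanniae (83.5), Cinnamomi (91.2), Sagunja (87.2) and Samul (87.6). The higher CA9 level at the low dose was thus not particular to Astragali, and code set and extract against vehicle cannot be separated. Hypoxia genes were lower as a list at the high than at the low dose of Astragali (1 of 19 called, 11 adjusted over the list alone, 0 higher), with an adjusted p of 7.9e-20 and of 0.000427 with an estimated correlation. The Astragali call of CA9 ended without Astragali high replicate 1 or 2 or Astragali low replicate 2 or 3. Each of these edgeR fits gave 0 genes, with 679 to 956 at an unadjusted p under 0.05, and DESeq2 with all libraries called 4. With all libraries the edgeR count under that p was 809 of 16979 genes. A share of 0.05 would reach such a p without any change, so these counts, and the 796 for Cnidii, lie near that share.

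Against vehicle, both had INSIG1 lower. With Cnidii it was at -0.51 ± 0.05 (log2). With Astragali INSIG1 was at 54.5 ± 0.751 CPM against 82.7 ± 6.07 (-0.60 ± 0.05) and the clock repressor NR1D2 at -0.60 ± 0.10, while the endothelial transcription factor KLF2 was higher by 0.57 ± 0.12. With Cnidii 470 genes were higher and 636 lower, and with Astragali 239 and 346, while without vehicle replicate 3 the totals were 47 and 37. Mitosis genes were lower with Astragali in 1 of 22 cases and higher in 0 (10 lower adjusted over the list alone), with an adjusted p of 7.4e-06 and of 0.0293 with an estimated correlation. NF-kB and inflammation genes were lower with Cnidii in 5 of 21 cases and higher in 0, such as RELB at -0.49 ± 0.12 (adjusted p = 0.000602, and 0.0918 with an estimated correlation). Of 12 named genes each, 4 with Cnidii and 4 with Astragali kept their call when any library was left out. Without vehicle replicate 3 LEFTY1 lost it in both (adjusted p = 0.0749 and 0.12), and NAV3 (0.0918) with Astragali.

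Mitochondrially encoded genes were lower than in vehicle with 5 of these extracts at the high dose, the change that went with vehicle replicate 3. Of 13 genes, 8 were lower with Cnidii, 5 with Rehmanniae, 2 with Astragali, 10 with Sagunja and 10 with Samul, and 0 were higher. By limma camera with an estimated correlation the adjusted p was 0.275, 0.273, 0.342, 0.264 and 0.243. MT-ATP8 with Samul was at 637.0 ± 65.3 CPM against 1584 ± 1319 in vehicle, and its call ended without vehicle replicate 3 (adjusted p = 0.47).

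Comparisons with the herbs of the formula asked how Samul differed from Cnidii and from Rehmanniae. Against Cnidii at the high dose Samul had 25 genes higher and 17 lower, with CYP1B1 higher by 0.55 ± 0.04, ALDH3A1 by 0.42 ± 0.05 and CYP1A1 by 2.71 ± 0.42. AHR targets were higher in 3 of 10 cases and lower in 0 (adjusted p = 7.4e-14, and 1.0e-06 with an estimated correlation). ID3, a repressor of differentiation, was at -0.40 ± 0.06. Against Rehmanniae Samul had 9 genes higher and 3 lower: the 3 lower genes were ID2 (-0.39 ± 0.08), ID3 (-0.31 ± 0.06) and the selenoprotein SELENOW (-0.34 ± 0.06). These comparisons lie between code sets. The noncoding gene ENSG00000280800, taken above as a measure of ribosomal RNA, was at 1862 ± 205 CPM in Samul. It was higher by 2.33 ± 0.32 against Cnidii and by 2.31 ± 0.31 against Rehmanniae. Leaving out 1 library gave 11 (without Samul high replicate 1) to 31 genes (without Cnidii high replicate 3) against Cnidii, and 5 (without Samul high replicate 1) to 22 (without Rehmanniae high replicate 3) against Rehmanniae. The fit of only the 6 libraries called 112 and 98 genes against Cnidii and Rehmanniae, and the fit without a low-count filter 171 and 190. The calls of ID2, ID3 and SELENOW against Rehmanniae ended without Samul high replicate 1 (adjusted p = 0.44, 0.44 and 0.168), those of ID2 and ID3 also without Rehmanniae high replicate 2 (0.56 and 0.0832) or 3 (0.0738 and 0.137), and those of ID2 and BTBD19 against Cnidii too (0.153 and 0.19).

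Cnidii and Rehmanniae, in 1 code set, differed in 24 genes at the high dose, 12 each way. CYP1B1 was lower with Cnidii (119.8 ± 3.64 against 152.4 ± 5.41 CPM, -0.35 ± 0.04), as was ALDH3A1 (-0.29 ± 0.05). AHR targets were lower in 2 of 10 cases and higher in 0 (adjusted p = 4.7e-07, and 0.000383 with an estimated correlation), and mitosis genes in 1 of 22 cases (13 adjusted over the list alone) and higher in 0 (1.3e-18 and 2.0e-06). The fit of only the 6 libraries called 48 genes, and the fit without a low-count filter 110. Left-out libraries gave 2 (without Cnidii high replicate 3) to 11 genes (without Cnidii high replicate 1), and the calls of CLDN2 (adjusted p = 0.0967), PTPRN2 (0.1), EREG (0.0967) and UGT1A1 (0.097), which shares reads with its gene cluster, ended without Cnidii high replicate 3. Each of these calls also ended without Rehmanniae high replicate 1, with adjusted p from 0.125 to 0.536.

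The responses of the extracts were compared across 16979 genes, which are not independent replicates. Between extracts the correlation of log2 changes from vehicle had a median of 0.654 over 15 pairs (0.422 to 0.731). Comparisons that share vehicle libraries and nothing else gave 0.499 in simulation with the spread of all libraries and 0.603 with that of the vehicle libraries, and the median covariance was 0.0582 against simulated values of 0.0256 and 0.0391. Between the high and the low dose, which share no library between extracts, the median was 0.031 (-0.038 to 0.162), the highest for Rehmanniae and Samul, and among 9947 abundant genes it was 0.178, with 0.579 for that pair. These 2 extracts shared 119 genes that rose with dose, where 2.15 were expected by chance, and Rehmanniae and Sagunja shared 48, where 0.853 were expected.

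Palmul at the high dose, with 1 library per dose and no test, had the Sagunja genes high. SAA2 was at 26.6, 25.5 and 17.4 CPM at the high, medium and low dose against 6.99 ± 1.60 in vehicle, CFB at 13.5, 11.8 and 8.77 against 4.82 ± 0.237, and CXCL8 at 4.47, 5.37 and 3.43 against 2.02 ± 0.424. RMRP, a noncoding RNA of an RNA-processing complex, was at 16.7, 6.50 and 2.43 CPM against 1.95 ± 1.13. CYP1B1 was at 169.8, 143.2 and 131.5 against 129.8 ± 4.56; it and CXCL8 and CFB were chosen after their values were seen. The list medians of the library at the high dose, as log2 differences from the vehicle mean, were 0.31 for AHR targets, 0.21 for DNA replication and -0.71 for mitochondrially encoded genes. At the medium and low dose the medians were 0.20 and 0.02 for AHR targets and 0.01 and -0.12 for DNA replication. For mitochondrially encoded genes they were -0.49 and -0.57. A single library gives no spread for these medians. Of the lowest genes, MT-ND6 was at 419.6 CPM against 1208.3 ± 894.6 in vehicle, whose spread comes from vehicle replicate 3.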

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

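The tests of a vehicle library that stands apart, for both the low doses and Sagunja, and the tests of code set for Cinnamomi and Sagunja were chosen only after the result was seen, as were the genes common to all comparisons and the gene name families. The same holds for the Sagunja genes whose values were compared over all replicated libraries.

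The change from the low to the high dose differed between Cinnamomi and Astragali in 5818 genes, and between Sagunja and Samul in 2 genes, ID3 and SELENOW, by the edgeR test of the difference itself. Between Cnidii and Rehmanniae it differed in 0 genes by edgeR, with 941 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0535; this difference was not run in DESeq2.

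Even the low doses differed from vehicle in 1080 to 2626 genes. This excess may come largely from 1 vehicle library, since without vehicle replicate 3 the calls left were at most 0.222 of the full number over the 6 extracts, while leaving out vehicle replicate 1 or 2 raised the number. Code set cannot be told apart from extract against vehicle: the mean covariance of low-dose changes within code sets exceeded that between them by 0.00179, inside the range of the pairs. A response to the extracts stays open: without that library SLC38A2 and KLF10 were higher in all 18 comparisons, with SLC38A2 at 317.2 to 391.6 CPM in 54 extract libraries and 286.6 to 290.8 in vehicle. These genes were chosen after their values were seen.

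Cinnamomi at the high dose lowered 1483 genes at least 2-fold. Neither GC content with gene length nor code set can be the whole cause: 94% of the genes with a known length and GC stayed at a log2 change of -1 or below after the median of their class was subtracted, and 86.5% were called lower against Astragali, of the same code set, as well. A dose-dependent response of the cells is a hypothesis that stays open, and 84% were also lower than at the low dose. Both shares reuse the 3 Cinnamomi high libraries that chose these genes, so they cannot tell a response from a fault of those libraries. The 3 libraries had 21621, 21987 and 20836 genes above 0, and no other library had fewer than 22058. A change in the make-up of the RNA, with TMM factors down to 0.869, was not tested and stays open. Reads shared between copies were not tested and may add to it, as 9 of 13 GOLGA6 and GOLGA8 genes and 16 of 19 NPIP genes were among them.

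Some NF-kB and inflammation genes were higher with Sagunja, although against vehicle at the high dose the list did not pass (adjusted p = 0.0518). A deviating vehicle library is argued against as the whole cause, since the list was also higher than with Samul, where no vehicle library enters, and without vehicle replicate 3 the highest adjusted p over the 3 doses was 0.0309 by limma camera, although with an estimated correlation it was 0.284. Code set is argued against by the comparison with Samul at the same dose, whose highest adjusted p was 8.3e-22 (1.97e-07 with an estimated correlation). The extract may raise part of these genes, but something else common to its 9 libraries stays open, because the list did not differ between the high and the low dose (adjusted p = 0.785).

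The 6 libraries of each comparison were also split into 3 and 3 in all 10 ways and fitted alone on the 16979 genes that passed the filter in the 57 libraries, and 10 splits are too few for a share under 0.05. The number of splits with as many genes as the real one was 1 for Cinnamomi against vehicle at the high dose (real value 6741, highest other 0) and medium dose (6 and 1), for Cnidii at the high and medium dose (3 and 0 each), for Rehmanniae at the high and low dose (3 and 0 each) and for Sagunja at the high, medium and low dose (3, 10 and 5, each with 0). It was also 1 for the high against the low dose of Rehmanniae (378 and 2), Cinnamomi (6250 and 0), Sagunja (344 and 4) and Samul (373 and 3). Among the pairs of extracts it was 1 for Cnidii and Rehmanniae (31 and 4), Cinnamomi and Astragali (7968 and 0), Sagunja and Samul (47 and 9), Samul and Cnidii (95 and 2) and Samul and Rehmanniae (74 and 2). It was 10, with a real value of 0, for Cnidii low (highest other 0), Rehmanniae medium (1), Cinnamomi low (1), Astragali high (1), medium (0) and low (2), and Samul high (0), medium (1) and low (0) against vehicle, and for Cnidii high against low (1). For Astragali high against low it was 2, with a real value of 3 and a highest other of 77, which points to a structure among these 6 libraries.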

How the results depend on the processing

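Leaving out the mitochondrial genes, leaving out vehicle replicate 3 and Cnidii high replicate 2 together, and the lists without vehicle replicate 3 were chosen after seeing the data. DESeq2 size factors and the fit without mitochondrial genes kept all counts of genes and lists within 1.5 times. The alternatives gave 9210 values for 765 pairs of a named gene and a comparison, so a gene can count more than once. Of these values 7921 kept their direction and call, 1288 kept the direction only, and 1 reversed. The reversed value was that of MT-ND1 with Cinnamomi high against vehicle. It ranged from -0.61 to 0.025 when 1 library was left out, the latter without vehicle replicate 3 (edgeR adjusted p = 0.911). Without that library 228 of the pairs lost their call. Only comparisons with vehicle were refitted without it, so these losses could lie nowhere else. Of the 765 pairs, 379 kept their call throughout. Where no cause is named, the cause was not tested. No comparison had a correlation above 0.1 for all 3 replicate numbers, but this cutoff cannot exclude a weaker pairing. In Sagunja high against low (0.084, 0.051 and 0.048) each library deviated most like the library of its own number. The same held for Sagunja against Samul at the high dose (0.044, 0.039 and 0.081), so pairing by number stays open. Depth limits genes of low count, some of which passed the filter, such as CYP1A1 at 0.248 CPM at the low dose of Samul.

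In the edgeR fit of only the 6 libraries, which has fewer samples and applied the filter to these 6, the counts against vehicle were 4, 3 and 0 for Cnidii (high, medium, low), 3, 0 and 3 for Rehmanniae, 9 and 0 for Cinnamomi medium and low, 0, 0 and 0 for Astragali, 3, 12 and 9 for Sagunja and 0, 0 and 0 for Samul; those of 0 had 1197 to 2311 genes at an unadjusted p under 0.05, and DESeq2 on 57 libraries called 951 to 2716. High against low gave 0 for Cnidii (630 at an unadjusted p under 0.05), 448 for Rehmanniae and 3 for Astragali, and pairs of extracts 48 (Cnidii, Rehmanniae), 112 (Samul, Cnidii) and 98 (Samul, Rehmanniae). Without any change, a share of 0.05 of the genes tested would reach an unadjusted p under 0.05. Without vehicle replicate 3 and Cnidii high replicate 2, which had 30504 genes above 0 where no other library had more than 24599, Cnidii high had 16 genes against vehicle, 1 against low and 21 against Samul. Without a low-count filter the counts were 1357 for Cnidii medium, 1067 for Rehmanniae high and 1204 for Astragali high against vehicle, 112 and 100 for high against low of Cnidii and Astragali, and 110 (Cnidii, Rehmanniae), 137 (Sagunja, Samul), 171 (Samul, Cnidii) and 190 (Samul, Rehmanniae) for pairs. DESeq2 gave 713 for Rehmanniae high and 951 for Astragali high against vehicle, 15 and 4 for high against low of Cnidii and Astragali, and 43, 86 and 22 for Cnidii and Rehmanniae, Samul and Cnidii, and Samul and Rehmanniae. A replicate block gave 598 for Rehmanniae high and 903 for Astragali high. With an estimated correlation 11 of 55 lists against vehicle at the high dose were called, 31 of 59 for high against low, 23 of 42 for pairs and 8 of 116 for the other doses, and also without vehicle replicate 3, 23 and 38. The similarity of responses (0.654) was 0.031 for high against low (0.178 among abundant genes) and 0.798 among abundant genes.

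Leaving out each library in turn gave, against vehicle at the high, medium and low dose, 47 to 2583, 35 to 2274 and 190 to 3136 for Cnidii, 55 to 1712, 31 to 2719 and 79 to 2390 for Rehmanniae, 37 to 2096, 50 to 3369 and 128 to 2926 for Astragali, 271 to 3621, 251 to 3332 and 583 to 3525 for Sagunja, 315 to 3115, 239 to 3633 and 329 to 3184 for Samul, and 8361 to 9252, 1045 to 4252 and 202 to 3620 for Cinnamomi. Except for Cinnamomi high, the lowest was without vehicle replicate 3 and the highest without vehicle replicate 1. High against low gave 0 to 5 for Cnidii, 107 to 162 for Rehmanniae, 0 to 3 for Astragali, 97 to 165 for Sagunja and 182 to 231 for Samul, and pairs 2 to 11 (Cnidii, Rehmanniae), 28 to 34 (Sagunja, Samul), 11 to 31 (Samul, Cnidii) and 5 to 22 (Samul, Rehmanniae). The similarity ranged from 0.589 to 0.767.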

Other observations

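The lists tested in this part were fixed before the data were examined, while the comparison of code sets and the chi-square between replicates came after values were seen. The interferon response list did not pass by limma camera at the high dose of Sagunja against vehicle (adjusted p = 0.34) or with dose in Samul (0.584). Ribosome biogenesis genes rose with the dose of Rehmanniae, with 1 of 20 called (4 adjusted over the list alone) and 0 lower (adjusted p = 9.5e-08, and 0.0247 with an estimated correlation). Hepatocyte marker genes fell with the dose of Sagunja in 3 of 6 cases and rose in 0: the fibrinogen chains FGA (-0.28 ± 0.04) and FGB (-0.23 ± 0.04) and the protease inhibitor SERPINA1 (-0.53 ± 0.10) (adjusted p = 6.1e-05, and 0.00107 with an estimated correlation). Heat shock genes were higher than in vehicle at the high dose of Sagunja in 5 of 12 cases and lower in 0 (adjusted p = 0.000874, and 0.0971 with an estimated correlation), with HSPA1B at 0.49 ± 0.07, which shares reads with HSPA1A. Fibroblast marker genes did not pass with Cinnamomi at the high dose (2 of 7 higher, 0 lower, adjusted p = 0.48).

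Between 2 libraries of a group the chi-square per degree of freedom was 2.45 to 58 over 57 pairs, with a median of 4.19. At the low dose, code sets 5 and 7 differed in 114 genes, 5 and 6 in 25, and 6 and 7 in 12.

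The correlation of log2 changes between extracts, 0.654 against vehicle, was 0.031 for high against low, where extracts share no library, and 0.178 there among abundant genes. Part of the excess over the simulated 0.499 may come from the shared controls, since the simulation with the spread of the vehicle libraries gave 0.603.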
